A study of Mus musculus with 7 samples.

How the data were processed

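Total RNA was extracted with TRIzol from primary myogenic progenitor cells of C57BL/6J hind limb muscle at passage 3, per the labels. Growth medium held 20% FBS and 10 ng/ml FGF-2 on collagen I. For differentiation, cells attached to ECL for 24 h in growth medium (day 0) and then received 2% horse serum. RNA with an integrity number above 9 was assayed on TaqMan rodent miRNA panels on a 7900HT instrument over 40 cycles. Software and settings for threshold and baseline are not given in the sources used here.

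The deposited files hold raw Ct values, per the file headers, for 381 assays (335 mouse, 40 rat, 5 endogenous control and 1 plant assay that was undetermined in all rows) in 4 rows per time. A time that occurs in several files was compared between them, and 8 of 8 repeats were identical. Ct values ran from 11.29 to 39.96, and 235 to 258 mouse assays per row were determined. The authors' processed table gives signed fold changes relative to MammU6 for 231 mouse assays, with 228 values in each comparison. Values recomputed from Ct lay within 0.01 log2 of the authors' fold change for 228 of 228 assays in each of the 7 comparisons. Sums of the differentiation comparisons closed within 0.1 log2 for 228 of 228 assays in each of 4 sums, which holds by construction since they share rows. The labels do not say whether the 4 rows are cultures or repeated measurements.

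Each Ct was subtracted from the MammU6 Ct of the same row, so that a higher value on this log2 scale is more miRNA. A mouse miRNA was tested in a comparison when at both times at least 3 of 4 rows were determined and the mean Ct was under 35. Tests were moderated t statistics as in limma 3.58.1 (R 4.3.3), fitted separately to the differentiation rows and the proliferation rows without a block, with missing values left out. The prior degrees of freedom were 4.45 and 7.87. P-values were adjusted by Benjamini and Hochberg within each comparison, and a miRNA was called at an adjusted p under 0.05. The course over differentiation days used the moderated F test, and the media were compared by the contrast of day 5 minus day 2 in differentiation against the same in proliferation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

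The tests, thresholds, miRNA lists and the first set of other settings listed below were chosen before the data were examined. The 14 lists are myomiRs, other miRNAs reported in myoblasts, miR-17 clusters, miR-15/16 family, let-7 family, Dlk1-Dio3 cluster, Sfmbt2 cluster, fibroblast and smooth muscle, blood cell, neuronal, epithelial, hepatic and pancreatic, endothelial, and the miR-290 and miR-302 clusters. A list was described where at least 3 members were measured, with counts adjusted over all assays and over the list alone. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. fry gives a p for a shared direction and a mixed p for changes either way. Unless called mixed, a fry p is that for a shared direction. Other lists hold 8 of the other myoblast assays, 3 of the miR-15/16 assays, 3 of the fibroblast assays and 2 of the blood cell assays.

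Named in each comparison were the measured myomiRs, the 8 largest rises and 8 largest falls among calls of at least 2-fold whose rows moved the same way, the 2 members of each other list with the largest absolute change, and miR-682, which published work by this group on the same cultures names. Only part of these is printed. Further miRNAs were named after their values were seen: let-7a, let-7g, miR-138, miR-218, miR-335-5p, miR-126-3p, miR-292-3p, members that complete a small count, those of the F test and the 10 of the difference between media.

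Whether rows at the same position in different times belong together was judged from the residuals before any calls with a block were compared. The lowest correlation between rows at the same position was 0.318, 0.128, 0.26, 0.283, 0.083 and 0.147 in the differentiation comparisons in the order reported, and 0.187 in proliferation. All were above 0.1 except that of day 5 over day 1, whose blocked counts are therefore given only among the alternatives. The highest correlation between rows at different positions was 0.2, 0.25, 0.275, 0.229, 0.15 and 0.303 in the same order, and 0.193 in proliferation. It exceeded the lowest same-position value except in day 1 over day 0 and day 5 over day 0. The files do not number the rows, so a match by position is only a hint from the data.

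The test was tried on simulated data with the mean and spread of each assay, with 30 assays shifted by log2 1 and 30 by log2 2 in each of 20 draws. Noise was drawn independently for each assay and row, so effects shared by a whole row were left out. The rates that follow therefore need not hold for the real rows. It found 34.7% of the smaller and 86% of the larger shifts in day 1 over day 0, 36.2% and 87.2% in day 5 over day 0, and 21% and 76% in proliferation, with 1.4 to 2 false calls on average in the 7 comparisons.

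Other settings tried were fold thresholds of 1.5 and 4, median centring, global-mean scaling, each other control alone (snoRNA135, snoRNA202, Y1, U87), no Ct filter, a Ct limit of 32, the series matrix values, ratios rebuilt from other comparisons, Welch's test per assay without moderation and leaving out each row. Added after the data were seen were the block by row position, rat assays, the mean of 3 controls, and further settings for the F test, the difference between media and named miRNAs. Rat and plant assays were left out of the tests, since the cells are from mouse. Other splits of the 8 rows of a comparison (35 each), and 100 random groupings for the F test (over all rows, and within row positions) and for the media, were counted with a fixed seed. Neighbouring hairpins were read from RefSeq genes of GRCm38.p6.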

Results

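Mature miRNAs were measured with TaqMan real-time PCR panels in primary myogenic progenitor cells, the cells that divide and then fuse into myotubes when muscle regenerates. The cells came from hind limb muscle of C57BL/6J mice and were used at passage 3. The study asked how miRNA levels change while such cells grow and while they differentiate. In the proliferation arm, cells were kept on collagen I in serum-rich growth medium with FGF-2 and sampled at day 2 and day 5. In the differentiation arm, cells attached to ECL for 24 h in growth medium (day 0) and were then switched to a medium with 2% horse serum. They were sampled at day 0, 1, 2 and 5. The 7 deposited samples are 7 comparisons of a pair of times, 6 of differentiation and 1 of proliferation. Each of the 6 times is represented by 4 rows of threshold cycles (Ct) for 335 mouse miRNA assays, of which 235 to 258 were determined in any row. The median Ct of a row was 24.82 to 26.3, and MammU6, the small nuclear RNA used as the reference, had a Ct of 12.3 to 13.85. No label says that the rows are separate cultures, so p-values measure only the spread between rows, which may be technical.

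Changes are log2 differences in level relative to MammU6 of the same row, with n = 4 rows per time, the standard error (SE) of the limma fit and its adjusted p. The median change over all tested miRNAs was itself away from 0. It was 0.06 for day 1 over day 0, 0.65 for day 2 over day 0, 0.59 for day 2 over day 1, 0.87 for day 5 over day 0, 0.76 for day 5 over day 1 and 0.16 for day 5 over day 2. For day 2 over day 5 of proliferation it was -0.73. The change of a miRNA list is therefore also given after this panel median was subtracted. The largest rises and falls named were chosen so that all rows of each time lay on the same side of the mean of the other time. The differentiation comparisons share rows and are not independent of one another. With a preset correlation of 0.01, camera called several lists, and each of these calls was lost when the correlation was estimated from the rows. With global-mean scaling, the muscle miRNA list kept its call under an estimated correlation, with adjusted p = 0.0184 for day 2 over day 0, 0.00585 for day 2 over day 1, 0.0277 for day 5 over day 0 and 0.0303 for day 5 over day 1. It did not for day 1 over day 0 (adjusted p = 0.157), day 5 over day 2 (adjusted p = 0.0843) or proliferation (adjusted p = 0.525). With MammU6, the fry adjusted p of this list was 6.57e-05 for day 2 over day 0 and 1.57e-06 for day 5 over day 0. For day 1 over day 0 it was 0.56. For day 5 over day 0, fry gave an adjusted p of 0.00597 for miR-17, 0.00495 for Dlk1-Dio3, 0.0023 for neuronal and 5.02e-04 for hepatic miRNAs. It gave 0.492 for the fibroblast and 0.279 for the blood cell list. fry compares members with 0, so a shift of the whole panel enters its p.

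The first comparison, day 1 over day 0, covers the first day in differentiation medium. The members of the miR-183, miR-96 and miR-182 cluster, which is best known from sensory organs and epithelia, rose together. The increase was 2.54 for miR-96 (SE 0.59, adjusted p = 0.0311), 1.48 for miR-182 (SE 0.26, adjusted p = 0.00622) and 1.2 for miR-183 (SE 0.29, adjusted p = 0.0311). miR-188-5p also rose by 1.26 (SE 0.30, adjusted p = 0.0311), and miR-685 fell by 1.33 (SE 0.28, adjusted p = 0.0226). Without row 2 of day 0, which lay apart, the increase of miR-96 was 1.69 (SE 0.32, adjusted p = 0.0145). These 5 were the only miRNAs called with MammU6 scaling and no row block, 4 higher and 1 lower of 224 tested. By limma with Y1 as the reference 0 were called (32 at an unadjusted p under 0.05), and by the unmoderated test 1.

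The cluster made up the 3 called members of the epithelial list, 3 of 6 both over all assays and adjusted over the list alone. Its median was 0.31, or 0.25 above the panel median, and -0.03 with Y1 as the reference (camera adjusted p = 0.208). None of the 6 measured striated muscle miRNAs (myomiRs) passed limma's test, 0 also when adjusted over the list alone and 0 by the unmoderated test, while 2 had an unadjusted p under 0.05. These were miR-133b at 0.93 (adjusted p = 0.344) and miR-486 at 1.33 (adjusted p = 0.223), both called with row position as a block (adjusted p = 0.00518 and 0.0316). With the global mean 1 of the 6 was called higher. For the list under that scaling the adjusted p was 0.00594 by fry and 0.0804 by camera. The blood cell list had a median of -0.96, or -1.02 against the panel (camera adjusted p = 0.00809, and adjusted p = 0.586 with an estimated correlation). None of its 6 members passed limma's test, 0 adjusted over the list alone and 0 by the unmoderated test, with 2 at an unadjusted p under 0.05. Its member miR-223, a myeloid miRNA, stood at -2.22 (SE 0.75, adjusted p = 0.198, or 0.0316 with the block). The block gave 16 higher and 9 lower, and the global mean 9 higher and 9 lower, without miR-182 (adjusted p = 0.0572) and miR-188-5p (adjusted p = 0.057). The count was 1 without row 1 of day 1 or row 3 of day 0, 2 without row 3 or row 4 of day 1, and 3 without row 2 of day 0.

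By day 2 over day 0, the miRNAs of striated muscle had risen. miR-499, which lies in an intron of the myosin heavy chain gene Myh7b, rose by 4.37 (SE 0.76, adjusted p = 3.61e-04). miR-486 rose by 3.50 (SE 0.48) and miR-1 by 3.30 (SE 0.45), each with adjusted p = 6.29e-05. At day 0 the mean Ct was 33.0 for miR-499 and 32.7 for miR-486. miR-133b rose by 2.39 (SE 0.39, adjusted p = 2.04e-04) and miR-133a by 2.26 (SE 0.30, adjusted p = 6.29e-05). The largest increase was that of miR-98, a let-7 relative, at 5.44 (SE 0.73, adjusted p = 6.29e-05). The largest fall was that of miR-582-5p, by 2.81 (SE 0.74, adjusted p = 0.00744), followed by miR-187, which fell by 2.23 (SE 0.32, adjusted p = 7.3e-05).

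In all, 5 of 6 myomiRs rose, 5 also adjusted over the list alone, with a median of 2.85, which was 2.20 above the panel (camera adjusted p = 0.00291, and adjusted p = 0.385 with an estimated correlation). The remaining one, miR-208b, stood at 0.93 (adjusted p = 0.116, or 0.0235 with the row block). Of 29 miRNAs from the imprinted Dlk1-Dio3 locus, 16 rose and none fell, among them miR-376a (2.23) and miR-431 (2.01). Adjusted over the list alone, 21 rose, against 26 of 29 with the block and 8 with the global mean. The median of this list was 1.2, or 0.55 above the panel (camera adjusted p = 0.00291, and adjusted p = 0.83 with an estimated correlation). In the let-7 family 3 of 9 rose, 3 adjusted over the list alone, with let-7f at 2.12 and let-7a at 1.62 beside miR-98, and 5 rose with the block. Among 26 other miRNAs reported in myoblasts, 5 rose and 2 fell, the same numbers as adjusted over the list alone, against 9 and 4 with the block and 6 and 11 with the global mean. miR-503 rose by 2.71 (SE 0.35, adjusted p = 6.29e-05) and its cluster neighbour miR-322, reported to promote cell cycle exit, by 1.86 (SE 0.37, adjusted p = 0.00101). miR-675-3p, made from the H19 transcript, rose by 2.11 (SE 0.48, adjusted p = 0.00304). The list's median was 0.07 and its mean 0.31, but camera pointed down (adjusted p = 0.192), and the median was -0.77 with Y1 as the reference.

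Of 7 neuronal miRNAs, 3 rose (3 adjusted over the list alone), miR-128a by 2.03, miR-9 by 1.51 and miR-138 by 1.37. In this list 3 were higher and 1 lower with the global mean, and 4 and 1 with the block. In the epithelial list 3 of 6 rose (3 adjusted over the list alone), with miR-96 at 3.70 and miR-182 at 1.78, against 3 higher and 2 lower with the global mean, although the list's median was 0.72 with MammU6 and -0.11 with Y1. In the miR-17 clusters, known for driving proliferation, miR-92a alone fell, by 1.29 (SE 0.30, adjusted p = 0.00331), 1 of 11 also when adjusted over the list alone and 9 of 11 with the global mean. Their median was 0.02 and their mean -0.14 (camera adjusted p = 0.017, and adjusted p = 0.83 with an estimated correlation), and the median was -0.82 with Y1. The blood cell list had a median of -0.79 (camera adjusted p = 0.00291, and adjusted p = 0.385 with an estimated correlation). Its member miR-155 fell by 1.02 (SE 0.34, adjusted p = 0.0294), 1 of 6 also adjusted over the list alone, against 4 with the block and 4 with the global mean. Over 224 tested miRNAs 62 were higher and 10 lower, 115 and 25 with the block, 46 and 56 with the global mean, 30 and 27 after median centring, and 19 and 29 with Y1 as the reference, and the unmoderated test called 37. The count of 72 dropped to 47 without row 3 of day 0.

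**Figure D1:**
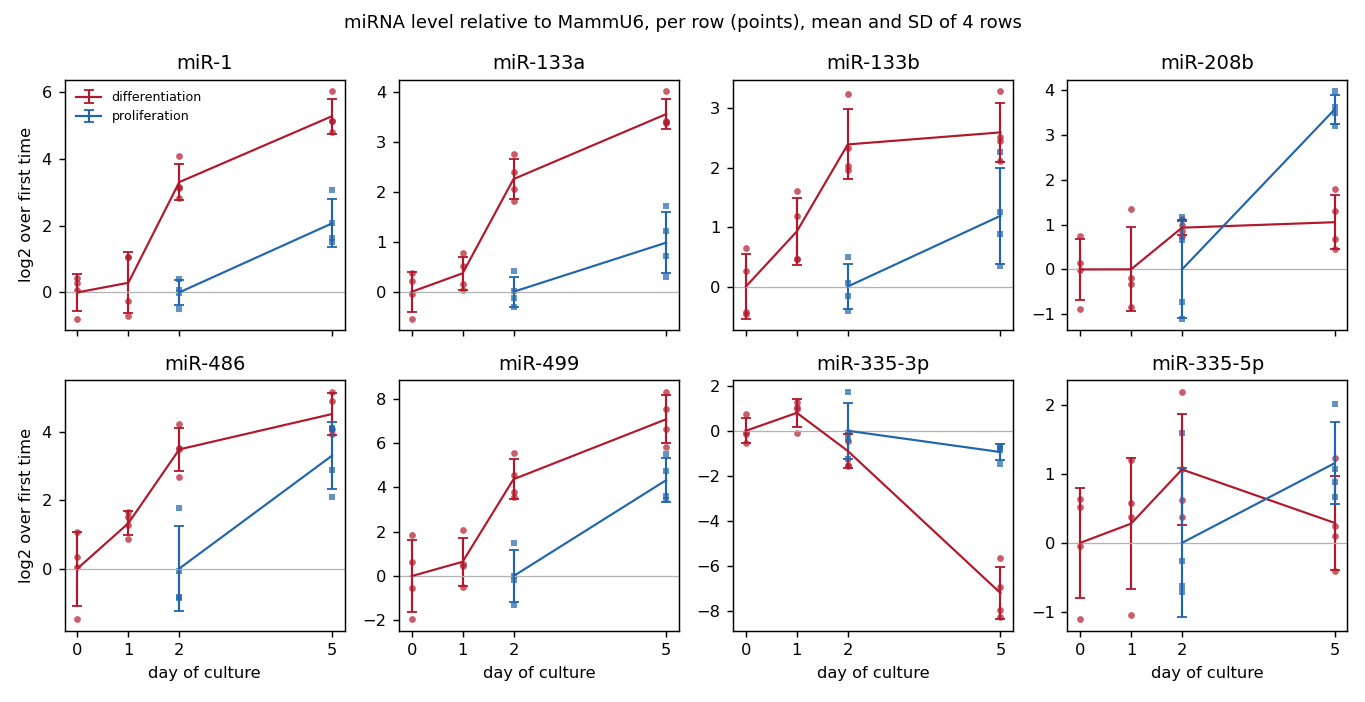
Log2 level relative to MammU6, over the mean of the first time of each culture, against day for 6 striated muscle miRNAs and both arms of miR-335. Points are the 4 rows of a time, and lines with bars are their mean and SD, in red for differentiation and in blue for proliferation. miR-499 reached a mean of 7.08 and miR-335-3p a mean of -7.19 at day 5 of differentiation.

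From day 1 to day 2, muscle miRNAs were among the largest rises. miR-499 rose by 3.73 (SE 0.76, adjusted p = 0.00536), miR-1 by 3.01 (SE 0.45, adjusted p = 9.14e-04), miR-486 by 2.17 (SE 0.48, adjusted p = 0.00879) and miR-133a by 1.89 (SE 0.30, adjusted p = 0.00124). Outside this list, miR-98 rose by 3.46 (SE 0.73, adjusted p = 0.00615), miR-10b of the Hox gene clusters by 2.70 (SE 0.53, adjusted p = 0.00451) and miR-139-5p by 1.71 (SE 0.29, adjusted p = 0.00179). miR-187 fell by 1.39 (SE 0.32, adjusted p = 0.0104) and miR-125b-3p by 1.11 (SE 0.29, adjusted p = 0.0203). No other miRNA was called lower with MammU6 scaling and no row block.

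Of the 6 myomiRs, 5 rose (5 adjusted over the list alone), with miR-133b at 1.47 (adjusted p = 0.024) and miR-208b not called at 0.93 (adjusted p = 0.188, or 0.0299 with the row block). The list's median was 2.03, or 1.44 above the panel (camera adjusted p = 1.52e-04, and adjusted p = 0.366 with an estimated correlation). In the Dlk1-Dio3 list 4 of 30 rose over all assays, including miR-329 (1.67) and miR-323-3p (1.54), 15 rose when adjusted over the list alone, 26 with the block and 2 with the global mean. Its median was 0.97, or 0.39 above the panel (camera adjusted p = 0.00147, and adjusted p = 0.822 with an estimated correlation). In the let-7 family miR-98 alone rose over all assays, 3 of 9 rose when adjusted over the list alone, and 9 with the block. miR-503 (1.67, adjusted p = 0.00615) and miR-322 (1.54, adjusted p = 0.0126) rose as well. The miR-17 clusters had a median of 0.00, or -0.58 against the panel, and a mean of -0.06 (camera adjusted p = 0.00387, and adjusted p = 0.822 with an estimated correlation). None of their 11 members passed limma's test, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by the unmoderated test, against 8 lower with the global mean. Over 225 tested miRNAs 22 were higher and 2 lower, 113 and 9 with the block, 19 and 29 with the global mean, 6 and 6 after median centring and 5 and 2 with Y1. By the unmoderated test 0 were called, with 50 at an unadjusted p under 0.05. The count of 24 was 14 and 15 without row 2 and row 3 of day 2, and 12 and 40 without row 3 and row 4 of day 1.

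Day 5 over day 0 spans the whole differentiation course. miR-499 rose by 7.08 (SE 0.76, adjusted p = 1.56e-06) and miR-1 by 5.27 (SE 0.45, adjusted p = 9.64e-08), its mean Ct going from 21.87 to 16.59. miR-10b rose by 5.22 (SE 0.53, adjusted p = 9.64e-07), miR-98 by 5.21 (SE 0.73, adjusted p = 2.74e-05) and miR-486 by 4.54 (SE 0.48, adjusted p = 1.56e-06). The rises of miR-499 and miR-486 start from low levels, with a mean Ct of 33.0 and 32.7 at day 0. The largest change among the miRNAs tested at both times was that of miR-335-3p, from the hairpin in the imprinted gene Mest, which fell by 7.19 (SE 0.53, adjusted p = 5.67e-08). The other arm of that hairpin, miR-335-5p, stood at 0.29 (SE 0.54, adjusted p = 0.648). The next largest falls were those of miR-15b at -2.99 (SE 0.37) and miR-92a at -2.42 (SE 0.30), each with adjusted p = 7.96e-06.

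All measured myomiRs but miR-208b rose, 5 of 6 over all assays and 6 of 6 adjusted over the list alone. Among them were miR-133a at 3.56 (SE 0.30, adjusted p = 9.64e-08) and miR-133b at 2.60 (SE 0.39, adjusted p = 5.87e-05), while miR-208b stood at 1.05 (adjusted p = 0.06, or 0.0108 with the row block). The list's median was 4.05, or 3.18 above the panel (camera adjusted p = 0.00195, and adjusted p = 0.468 with an estimated correlation). Of the 11 miR-17 cluster members 6 fell, 6 also adjusted over the list alone and 11 with the global mean, among them miR-92a and miR-106a at -1.43. Their median was -1.07, or -1.94 against the panel (camera adjusted p = 1.66e-06, and adjusted p = 0.468 with an estimated correlation). In the miR-15/16 family, which restrains cyclins, miR-15b, miR-16 (-1.52) and miR-195 (-1.32) fell and miR-322 rose by 0.96 (adjusted p = 0.0387, but 0.619 with the global mean), 1 higher and 3 lower of 6, the same when adjusted over the list alone. Its median was -1.0, or -1.86 against the panel (camera adjusted p = 0.00593, and adjusted p = 0.468 with an estimated correlation).

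In the let-7 family 4 of 9 rose (4 adjusted over the list alone, 7 with the block), namely miR-98, let-7f at 2.93, let-7a at 1.92 and let-7g at 1.5. Of the 29 Dlk1-Dio3 miRNAs 20 rose and none fell, 20 also adjusted over the list alone, with miR-382 at 2.96 and miR-136 at 2.40. With the global mean 9 of them were higher and 2 lower, and the median of 1.2 was 0.34 above the panel (camera adjusted p = 0.124). Of 5 measured miRNAs from the Sfmbt2 intron 4 rose (4 adjusted over the list alone, 2 with the global mean), the largest change being that of miR-669a at 2.70. Of the 26 other miRNAs reported in myoblasts 8 rose and 3 fell, 8 and 3 also adjusted over the list alone, 11 and 8 with the block, and 7 and 12 with the global mean. The largest increases among these were miR-675-3p at 2.26 and miR-27b, reported to target Pax3, at 2.07. Their median was 0.24, against -0.63 after median centring, and camera pointed down (adjusted p = 0.145) while the mean was 0.31. By fry the list was not called for a shared direction (adjusted p = 0.463) but was for changes either way (mixed adjusted p = 8.9e-06).

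Markers of other cell types did not all move one way. All 4 measured hepatic and pancreatic miRNAs rose (4 adjusted over the list alone), with the islet miRNA miR-375 at 2.52 (SE 0.64, adjusted p = 0.00448) and miR-194 at 2.23 (camera adjusted p = 0.128). With the global mean 3 of the 4 were called higher, and the unmoderated test called 3. Of 7 neuronal miRNAs 4 rose (4 adjusted over the list alone), miR-9 by 3.28, miR-128a by 3.11, miR-138 by 1.93 and miR-218 by 1.27, the last not called with the global mean (adjusted p = 0.307, camera for the list adjusted p = 0.252). In this list 3 were higher and 1 lower with the global mean, and 5 and 1 with the block. In the epithelial list miR-96 (2.85) and miR-183 (1.56) rose, 2 of 6 also adjusted over the list alone, against 1 higher and 2 lower with the global mean. Its median was 0.75 with MammU6 and -0.12 after median centring, and miR-183 was not called with the global mean (adjusted p = 0.0553). In the blood cell list miR-155 fell by 1.16 (SE 0.34, adjusted p = 0.00997), 1 of 6 also adjusted over the list alone and 3 with the global mean, while the median was 0.14, the mean -0.02 and the median after centring -0.73 (camera adjusted p = 0.128). None of the 6 fibroblast and smooth muscle miRNAs passed limma's test, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by the unmoderated test, against 2 higher with the block and 2 lower with the global mean. Their median was 0.32 with MammU6 and -0.55 after median centring. Both miR-126 assays, the endothelial list, were measured and neither was called by limma, miR-126-3p standing at 0.86 (adjusted p = 0.0717, or 0.00248 with the block). None of the 12 assays of the pluripotent cell clusters miR-290 and miR-302 was measured at both times. miR-682, named in published work on such cultures, stood at -0.02 (SE 0.69, adjusted p = 0.979).

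Over the 227 miRNAs tested for day 5 over day 0, 95 were higher and 22 lower, of which 109 changed at least 2-fold. The split was 65 higher and 61 lower with the global mean, 31 and 44 after median centring and 64 and 49 with snoRNA202 as the reference. No miRNA called with MammU6 was called in the opposite direction with any of these 3 scalings. The 4 other small RNA controls lay between 0.10 (snoRNA135) and 0.68 (snoRNA202) relative to MammU6.

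**Figure D2:**
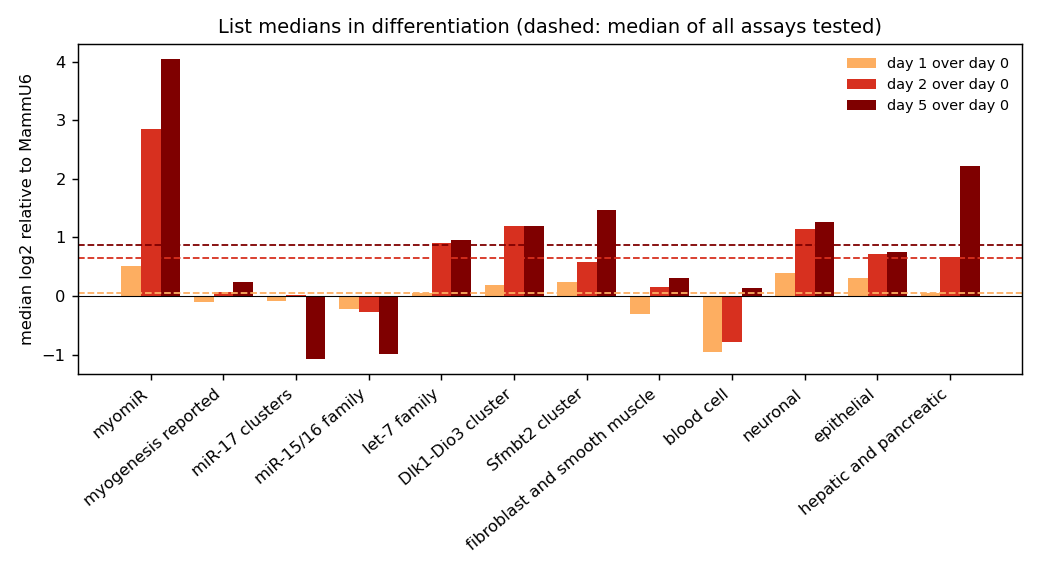
Median log2 change relative to MammU6 of 12 miRNA lists at day 1, 2 and 5 over day 0, with dashed lines at the panel medians of 0.06, 0.65 and 0.87. The myomiR median rose to 4.05 and the miR-17 cluster median reached -1.07 at day 5, while other scalings turn the sign of the other myoblast, fibroblast, blood cell and epithelial lists at day 5. They also turn the other myoblast, miR-17, Sfmbt2, fibroblast, epithelial and hepatic lists at day 2, and the miR-17, let-7, Dlk1-Dio3, Sfmbt2, epithelial and hepatic lists at day 1.

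From day 1 to day 5 the striated muscle miRNAs miR-499 and miR-1 were again among the largest rises. miR-499 rose by 6.43 (SE 0.76, adjusted p = 6.58e-06), miR-10b by 5.57 (SE 0.53, adjusted p = 5.6e-07) and miR-1 by 4.99 (SE 0.45, adjusted p = 4.83e-07). miR-598 rose by 3.79 (SE 0.62, adjusted p = 1.89e-04) and miR-375 by 3.36 (SE 0.64, adjusted p = 7.75e-04). miR-335-3p fell by 7.98 (SE 0.53, adjusted p = 1.13e-08), miR-15b by 2.67 (SE 0.37, adjusted p = 4.61e-05) and miR-92a by 1.71 (SE 0.30, adjusted p = 3.29e-04). The brain and islet miRNA miR-7a fell by 1.57 (SE 0.41, adjusted p = 0.00717) and miR-7b by 1.32 (SE 0.38, adjusted p = 0.0116).

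Of the 6 myomiRs 5 rose over all assays and 6 adjusted over the list alone, with a median of 3.20, or 2.44 above the panel (camera adjusted p = 0.00164, and adjusted p = 0.341 with an estimated correlation). The miR-17 clusters again had 6 of 11 members lower, 6 adjusted over the list alone and 11 with the global mean, and a median of -0.96, or -1.72 against the panel. Their camera adjusted p was 2.63e-07, and adjusted p = 0.341 with an estimated correlation. The miR-15/16 family had 3 of 6 lower (3 adjusted over the list alone, 5 with the global mean, camera adjusted p = 0.00173, and adjusted p = 0.341 with an estimated correlation). Of the Dlk1-Dio3 list 14 of 29 rose (14 adjusted over the list alone), against 7 higher and 2 lower with the global mean, and 5 of 9 let-7 miRNAs rose (5 adjusted over the list alone). Among other myoblast miRNAs, miR-181a rose by 1.99 (SE 0.50, adjusted p = 0.00486) and miR-27b by 1.84 (SE 0.45, adjusted p = 0.00406). In that list 6 of 26 rose and 2 fell, as adjusted over the list alone, against 5 and 12 with the global mean. Its median was 0.24 with MammU6 and -0.48 with the global mean, and camera pointed down (adjusted p = 0.269). In the epithelial list miR-200c rose by 1.5 (adjusted p = 0.0193, but 0.0702 with the global mean) and miR-182 fell by 0.88 (SE 0.26, adjusted p = 0.013), 1 higher and 1 lower of 6, against 2 lower with the global mean. miR-451 of red blood cells rose by 2.42 (adjusted p = 0.0341, but 0.0865 with the global mean). In the blood cell list 2 of 6 were higher (3 adjusted over the list alone), against 2 lower with the global mean. Both endothelial assays were called higher, with miR-126-3p at 1.29 (SE 0.38, adjusted p = 0.013). Over 224 tested miRNAs 77 were higher and 16 lower, 56 and 56 with the global mean and 24 and 36 after median centring, and the unmoderated test called 57. The count of 93 dropped to 61 without row 2 of day 1.

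Between day 2 and day 5 the panel median moved by 0.16, and rises and falls were more even. miR-375 rose by 3.57 (SE 0.64, adjusted p = 0.00223), miR-330 by 3.25 (SE 0.70, adjusted p = 0.00705), miR-10b by 2.88 (SE 0.53, adjusted p = 0.00227) and miR-672 by 2.82 (SE 0.55, adjusted p = 0.00335). Among the myomiRs miR-499 rose by a further 2.71 (SE 0.76, adjusted p = 0.0243), miR-1 by 1.97 (SE 0.45, adjusted p = 0.00705) and miR-133a by 1.30 (SE 0.30, adjusted p = 0.00818). miR-335-3p fell by 6.29 (SE 0.53, adjusted p = 4.18e-07) and miR-15b by 2.25 (SE 0.37, adjusted p = 0.00115). miR-351 fell by 1.40 (SE 0.31, adjusted p = 0.00651) and its cluster neighbour miR-503 by 1.17 (SE 0.35, adjusted p = 0.0369).

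Thus 3 of 6 myomiRs rose, 3 also adjusted over the list alone, while miR-486 stood at 1.04 (adjusted p = 0.171, or 0.0353 with the row block), miR-133b at 0.20 and miR-208b at 0.12 (-0.03 with the global mean). The myomiR median was 1.17, or 1.02 above the panel (camera adjusted p = 0.0249, or 0.0894 with the block, and adjusted p = 0.509 with an estimated correlation). In the miR-17 clusters 2 of 11 fell over all assays, miR-18a by 1.17 and miR-92a by 1.13, against 8 adjusted over the list alone, 10 with the block and 11 with the global mean. Their median was -0.86 (camera adjusted p = 1.66e-05, and adjusted p = 0.435 with an estimated correlation). In the miR-15/16 family miR-15b and miR-195 (-1.14) fell, 2 of 6, against 4 adjusted over the list alone, 4 with the block and 4 with the global mean (camera adjusted p = 0.00135, and adjusted p = 0.435 with an estimated correlation). Of the 4 hepatic and pancreatic miRNAs 3 rose (3 adjusted over the list alone), miR-375, miR-194 by 1.60 and miR-192 by 1.31. Their median was 1.55 (camera adjusted p = 0.00257, and adjusted p = 0.435 with an estimated correlation). miR-146b rose by 1.58 (SE 0.32, adjusted p = 0.00479) and miR-9 by 1.76 (SE 0.42, adjusted p = 0.00928). Of the 26 other myoblast miRNAs 1 rose and 2 fell, 3 and 2 adjusted over the list alone and 5 and 9 with the global mean. In the Dlk1-Dio3 list miR-666-5p rose by 2.53 (adjusted p = 0.0233, but 0.0561 with the global mean) and miR-370 (-1.10) and miR-431 (-1.04) fell, 1 higher and 2 lower of 32, as adjusted over the list alone, against 1 and 6 with the global mean. Over 229 tested miRNAs 17 were higher and 11 lower, 52 and 35 with the block, 38 and 44 with the global mean, and between 49 and 2 with Y1 and 26 and 50 with snoRNA202. The count of 28 was 16 without row 2 of day 5, and 48 and 18 without row 1 and row 4 of day 2.

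**Figure D3:**
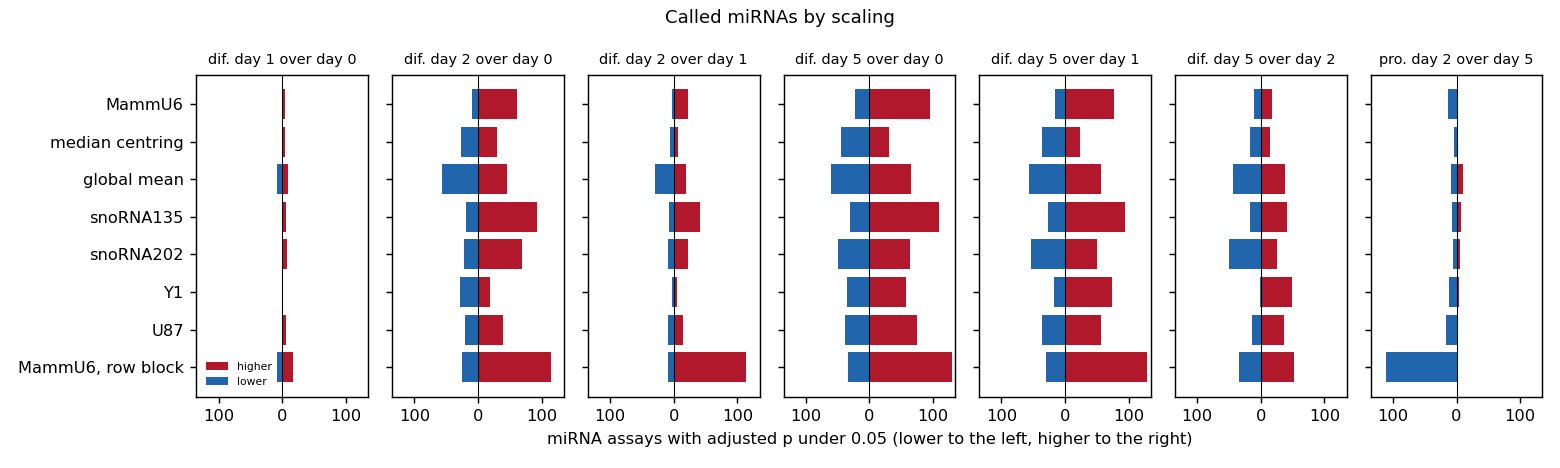
Number of miRNAs called higher (right) and lower (left) at an adjusted p under 0.05 in each of the 7 comparisons, by reference or scaling, with the row block in the last bar. For day 5 over day 0 the split was 95 higher and 22 lower with MammU6 and 65 and 61 with the global mean. After median centring it was 31 higher and 44 lower. Of the scalings shown, only centring, which sets the panel median to 0, gave more lower than higher calls in this comparison.

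Over all 4 days of differentiation, limma's moderated F test called 121 of 217 miRNAs. The smallest adjusted p values belonged to miR-335-3p (3.04e-09), miR-1 (4.87e-08), miR-133a and miR-139-5p (9.95e-08 each) and miR-10b (1.98e-07). miR-335-3p stood at 0.79 at day 1, -0.89 at day 2 and -7.19 at day 5 over day 0. miR-139-5p stood at 0.44, 2.14 and 3.48 on the same days. miR-10b went from -0.35 to 2.35 and 5.22, and miR-1 from 0.29 to 3.30 and 5.27. Without row 2, row 3 or row 4 of every day the count was 71, 67 or 73.

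In growth medium, day 2 was compared with day 5, so a negative value means a higher level at day 5. Muscle miRNAs were lower at day 2. miR-499 fell by 4.33 on this scale (SE 0.62) and miR-208b by 3.57 (SE 0.52), each with adjusted p = 9.7e-04. The change was -3.31 for miR-486 (SE 0.64, adjusted p = 0.00797) and -2.07 for miR-1 (SE 0.45, adjusted p = 0.0127). The mean Ct at day 2 was 33.0 for miR-499, 32.9 for miR-208b and 33.8 for miR-486, so their changes start from low levels. let-7f stood at -3.06 (SE 0.61, adjusted p = 0.00802), miR-708 at -3.06 (SE 0.63, adjusted p = 0.00802) and miR-135a at -3.00 (SE 0.53, adjusted p = 0.00455). With MammU6 scaling and no row block, miR-682 was the only miRNA called higher at day 2, by 2.15 (SE 0.50, adjusted p = 0.0192).

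Of the 6 myomiRs 4 were lower at day 2 over all assays and 6 adjusted over the list alone. Their median was -2.69, or -1.96 against the panel (camera adjusted p = 1.08e-04, or 0.0962 with the row block, and adjusted p = 0.594 with an estimated correlation). miR-133a stood at -0.98 (adjusted p = 0.144) and miR-133b at -1.19 (adjusted p = 0.126, or 0.0261 with the block). In the let-7 family 3 of 9 were lower, 3 adjusted over the list alone, 9 with the block and 1 with the global mean, namely let-7f, let-7a (-2.44, with the global mean adjusted p = 0.0534) and miR-98 (-3.53, adjusted p = 0.0266, but 0.083 with the global mean). Their median was -1.09, or -0.36 against the panel (camera adjusted p = 0.0965, or 0.0435 with the block, and with the block adjusted p = 0.877 with an estimated correlation). In the Dlk1-Dio3 list the median was -0.36 with MammU6 and 0.58 with snoRNA202, and camera pointed up (adjusted p = 0.0486, and adjusted p = 0.888 with an estimated correlation). None of its 29 members passed limma's test, 0 adjusted over the list alone and 0 by the unmoderated test, with 4 at an unadjusted p under 0.05 and 6 lower with the block. Of the miR-290 and miR-302 assays only miR-292-3p was measured here, at -1.76 (SE 0.94, adjusted p = 0.21). Over 226 tested miRNAs 1 was higher and 14 lower, 3 and 111 with the block, 10 and 9 with the global mean, 2 and 4 after median centring, and 7 and 7 with snoRNA135 as the reference. By the unmoderated test 0 were called, with 41 at an unadjusted p under 0.05. The count of 15 was 84 without row 2 of day 2 and 9 without row 2 of day 5.

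The last comparison set the change from day 2 to day 5 in differentiation medium against that in growth medium, here both as day 5 minus day 2. The arms also differ in coating, ECL against collagen I, so effects of medium and coating cannot be told apart. miR-335-3p changed by -6.29 in differentiation medium and -0.94 in growth medium, a difference of -5.35 (SE 0.83, adjusted p = 6.18e-04). miR-208b stood at 0.12 and 3.57, a difference of -3.45 (SE 0.63, adjusted p = 0.00248). Its level at day 2 in growth medium was low, with a mean Ct of 32.9. miR-503 and miR-322 were at -1.17 and -0.90 in differentiation medium and at 1.53 and 1.52 in growth medium, with differences of -2.70 (SE 0.53, adjusted p = 0.0033) and -2.42 (SE 0.53, adjusted p = 0.00705). miR-15b differed by -2.97 (SE 0.68, adjusted p = 0.00907) and miR-195 by -1.77 (SE 0.47, adjusted p = 0.0349). In the opposite sense, miR-672 differed by 3.44 (SE 0.67, adjusted p = 0.0033) and miR-146a by 1.93 (SE 0.54, adjusted p = 0.0434).

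The other called differences were those of miR-135a at -2.98 (SE 0.66, adjusted p = 0.00705) and miR-197 at -3.28 (SE 0.91, adjusted p = 0.0424), and miR-682 differed by 2.32 (adjusted p = 0.0624). In all, 10 of 212 miRNAs differed, 2 with the change in differentiation medium higher and 8 with it lower, and 50 had an unadjusted p under 0.05. The median change was 0.14 in differentiation medium and 0.74 in growth medium. Across assays, which are not independent replicates, the changes in both media had a Spearman rho of 0.241 and a Pearson r of 0.282, and 130 of 212 (61.3%) had the same sign. After each change was centred on its median, 124 (58.5%) did. The count of 10 called differences was 97 with the row block and 36 with the global mean. Without row 2, row 3 or row 4 of every time it was 26, 2 or 3, while the rho was 0.12 without row 2.

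**Figure D4:**
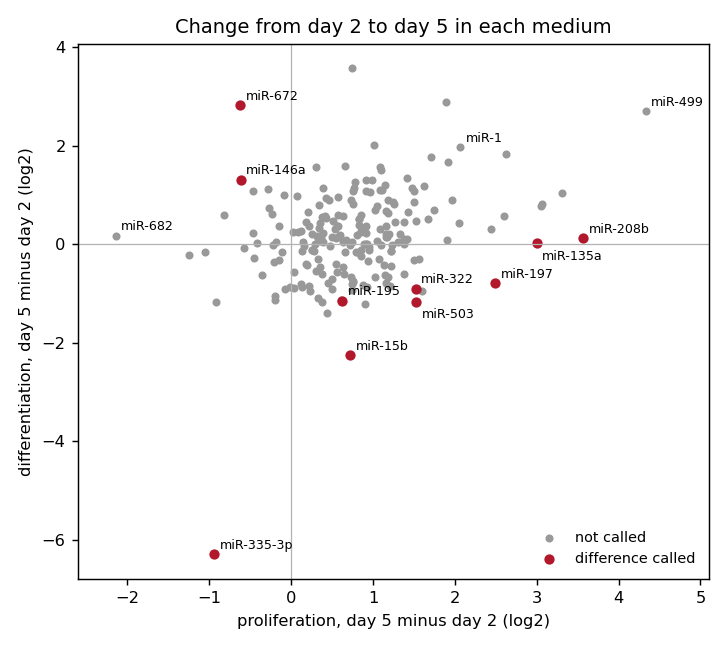
Log2 change from day 2 to day 5 relative to MammU6 in growth medium (x axis) and in differentiation medium (y axis), 1 point per miRNA, with the 10 whose difference was called in red. miR-335-3p lies lowest at -6.29, and the median changes of 0.74 and 0.14 depend on the scaling.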

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

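The tests on the panel shift against the other controls, on the Ct of miR-335-3p, on scaling and exchanged rows in growth medium, on the levels of miR-208b and miR-135a there, and on days redrawn within row positions were chosen after the result was seen, as was the search for assays present at only some times.

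Of 344 groups of 4 rows examined, 24 (6.98%) held a row far from the other 3, where chance gives about 1 in 20. Among Ct values these were Y1 at 22.67 in row 3 of day 0 and MammU6 at 13.85 in row 1 of day 2 of differentiation. Among levels relative to MammU6 at day 0 they were miR-96 at -22.71 (row 2), miR-214 at -6.24 (row 1) and miR-10b at -16.72 (row 3). At day 1 they were miR-375 at -18.02 and miR-181a at -11.79 (row 1) and miR-682 at -21.42 (row 4). At day 2 they were miR-672 at -14.92, miR-675-3p at -9.98 and miR-128a at -8.08 (row 1) and miR-376a at -12.62 (row 4). At day 5 they were miR-133a at 1.89, miR-128a at -7.06 and miR-195 at -11.26 (row 1) and miR-685 at -10.71 (row 2). In proliferation at day 2, row 2 held miR-135a at -13.71, miR-106b at -6.89, miR-19b at -2.24, miR-381 at -17.93 and miR-128a at -10.99, and row 4 held miR-215 at -20.51. At day 5 of proliferation row 2 held miR-142-3p at -16.75 and miR-192 at -10.20. Row 1 of differentiation held 10 and row 2 of proliferation 7 of the 24, and MammU6 had its highest Ct in these rows at each time. snoRNA202 did not. In row 1 of day 2 of differentiation MammU6 was at 13.85 against 12.51 to 12.73, and snoRNA202 at 15.19 against 14.72 to 15.56. In row 2 of day 2 of proliferation they were at 13.61 against 12.43 to 12.72 and at 15.05 against 15.38 to 15.78. All levels flagged in these rows lay above those of the other 3, as a late MammU6 would give. Why MammU6 was late was not tested.

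The change from day 2 to day 5 differed between media for 10 miRNAs, by -5.35 for miR-335-3p, -3.45 for miR-208b, 3.44 for miR-672, -2.70 for miR-503, -2.42 for miR-322, -2.98 for miR-135a, -2.97 for miR-15b, -1.77 for miR-195, -3.28 for miR-197 and 1.93 for miR-146a. Chance was not excluded for this count, since 5 of 100 groupings, the real one included, called at least as many, and the highest other called 96. A grouping that calls so many more points to structure among the rows. The groupings did not keep rows at the same position together, so they cannot decide this if such rows belong together. With the row block the count was higher, as given above.

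For the called counts of single comparisons, if all 35 splits of the 8 rows are exchangeable, chance could be excluded in each differentiation comparison, where only 1 split, the real one, reached its count. The real and highest other counts were 5 and 1 for day 1 over day 0, 72 and 2 for day 2 over day 0, 24 and 1 for day 2 over day 1, 117 and 74 for day 5 over day 0, 93 and 0 for day 5 over day 1, and 28 and 1 for day 5 over day 2. The split with 74 set row 1 of day 0 and rows 1, 2 and 4 of day 5 against the rest. Chance between rows could be excluded for the F test as well (121, highest other 48), also when days were redrawn only within each row position (highest other 54). The labels do not say whether the rows are cultures. If they are repeated measurements, none of these counts excludes chance between cultures. In proliferation chance between rows was not excluded, since 2 of 35 splits reached 15 calls. The other gave 79 and set rows 1, 3 and 4 of day 2 with row 4 of day 5 apart. It thus exchanges row 2 of day 2 with row 4 of day 5, and its higher count points to structure among the rows. If rows at the same position belong together, which the files do not say, only the 8 splits that part all positions count. These are too few for a share under 0.05 in any comparison, and the highest other among them gave 0 in each of the 7.

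The panel median moved by 0.87 in day 5 over day 0 and by -0.73 in day 2 over day 5 of proliferation. If MammU6 alone had moved at day 5 of differentiation, the 4 other controls would show the whole shift, but their mean was 0.43 (SE 0.12), which argues against it as the whole cause. In proliferation their mean was -0.59 (SE 0.19), so this test did not exclude a drift of MammU6 there. The controls were uneven, with snoRNA135 at -0.78, snoRNA202 at -0.935 and Y1 at -0.605, but U87 at -0.05 (SE of rows 0.47). The raw Ct of MammU6 hardly moved, at 12.85 at day 2 and 12.88 at day 5. Without a measure of RNA input, raw Ct cannot show whether MammU6 or the other RNAs moved. Weakly amplified assays are argued against in both, since assays with a mean Ct under 28 moved by 0.73 and -0.72. A general change in miRNA abundance or RNA recovery at day 5 of differentiation stays open.

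miR-335-3p fell by 7.19 from day 0 to day 5 while miR-335-5p stood at 0.29. A single aberrant row is argued against, since the smallest change with 1 row left out was -6.84. Loss near the cycle limit is argued against by the highest day 5 Ct of 28.57, and a general habit of hairpin arms by the 17 other arm pairs, whose highest difference was 2.27 against 7.47 here. A difference in processing or decay between the arms and a fault of the assay both stay open, and neither was tested.

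The myomiRs were higher at day 5 than at day 2 in growth medium, with a median of 2.69. Of these, miR-499, miR-486 and miR-208b had low levels at day 2, with a mean Ct of 33.0, 33.8 and 32.9. The scaling is argued against as the cause by a median of 1.93 with the global mean, and an exchange with day 5 of differentiation by a change of miR-335-3p of -0.94 only. The 81 other miRNAs that rise in differentiation exceeded the panel median by 0.35, against at most 0.18 in 1000 random lists. Of these 81, 53 lay above the panel median. The Dlk1-Dio3 list, which rises in differentiation, went the other way, its median for day 2 over day 5 lying 0.375 above the panel. Random lists treat assays as independent and were not matched on abundance, so this test cannot decide. Differentiation of part of the cells in growth medium stays open. It does not account for miR-135a, which lay 3.74 (SE 0.60) above its highest mean level in differentiation. miR-208b lay 0.54 (SE 0.34) above its own highest level there, which by the rule set neither excludes nor favours such a share. In the other measured myomiRs every row at day 5 in growth medium lay below every row at day 5 of differentiation. For miR-1 these were -7.99 to -6.42 against -4.08 to -2.87, but for miR-208b -16.87 to -16.1 against -17.64 to -16.31. This argues against a share of the size that miR-1 allows as the whole cause for miR-208b.

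Some assays were determined in all 4 rows of one time and in none of another. miR-139-3p had a mean Ct of 37.96 at day 2 and 34.23 at day 5 of differentiation and was undetermined at day 0, and miR-302b had 32.75 at day 5 and was undetermined at days 0, 1 and 2. miR-291a-3p had 35.66 at day 5 of proliferation and was undetermined at day 2. Of 10 rat assays tested in day 5 over day 0, 4 were called, at 4.54 for rat miR-1, 3.35 for miR-339-3p, 2.42 for miR-450a and 1.87 for miR-532-5p.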

How the results depend on the processing

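The row block, the rat assays, the mean of 3 controls, and all settings for the F test and most for the difference between media were tests chosen after the data were seen.

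For day 1 over day 0 the count of 5 became 18 with the global mean, 8 with snoRNA202, 0 by limma with Y1 (32 at an unadjusted p under 0.05), 1 by Welch's test, 25 with the row block, 14 with the mean of 3 controls and 1 to 6 without 1 row. The rows that moved it most were row 1 of day 1 and row 3 of day 0 (1 each), rows 3 and 4 of day 1 (2 each) and row 2 of day 0 (3). For day 2 over day 0 the count of 72 became 111 with snoRNA135, 37 by Welch's test, 140 with the block, 116 with 3 controls and 47 to 105 without 1 row, with 47 lacking row 3 of day 0. For day 2 over day 1 the count of 24 became 12 after median centring, 48 with the global mean, 49 with snoRNA135, 7 with Y1, 122 with the block and 58 with 3 controls. By Welch's test it was 0, with 50 at an unadjusted p under 0.05. Without 1 row it was 12 to 40, namely 14 and 15 without rows 2 and 3 of day 2, and 12 and 40 without rows 3 and 4 of day 1.

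For day 5 over day 0 the count of 117 became 75 after median centring and was at least 93 without any 1 row. For day 5 over day 1 the count of 93 became 60 after centring, 57 by Welch's test, 159 with the block and 61 to 99 without 1 row, 61 lacking row 2 of day 1. For day 5 over day 2 the count of 28 became 82 with the global mean, 58 with snoRNA135, 76 with snoRNA202, 51 with Y1, 50 with U87, 87 with the block and 73 with 3 controls. Without 1 row it was 16 to 48, namely 16 without row 2 of day 5, and 48 and 18 without rows 1 and 4 of day 2.

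In proliferation the count of 15 became 6 after centring, 114 with the block and 24 with rat assays, and by Welch's test it was 0, with 41 at an unadjusted p under 0.05. Without 1 row it was 9 to 84, with 84 lacking row 2 of day 2 and 9 lacking row 2 of day 5. The F test count of 121 was 67 to 139 without 1 row position, with 71, 67 and 73 without positions 2, 3 and 4. The difference between media, 10 miRNAs, was 36 with the global mean, 97 with the block and 2 to 26 without 1 row position, 26, 2 and 3 without positions 2, 3 and 4. The Spearman rho of 0.241 was 0.12 to 0.331 without 1 position, with 0.12 lacking position 2.

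Of 84 list medians, 29 changed sign after centring, 4 of them with an adjusted p under 0.05 by fry before or after. After centring, in day 1 over day 0 the let-7 median was -0.012. In day 2 over day 0 it was -0.58 for other myoblast miRNAs, -0.63 for miR-17 clusters, -0.075 for Sfmbt2 and -0.49 for fibroblast. In day 2 over day 1 it was -0.29 for other myoblast miRNAs, -0.58 for miR-17, -0.57 for miR-15/16, -0.49 for blood cell, -0.24 for epithelial and -0.099 for hepatic. In day 5 over day 0 it was -0.63 for other myoblast miRNAs, -0.55 for fibroblast, -0.73 for blood cell and -0.12 for epithelial. In day 5 over day 1 it was -0.515 for other myoblast miRNAs, -0.126 for fibroblast and -0.522 for epithelial. In day 5 over day 2 it was -0.1 for other myoblast miRNAs, -0.084 for Dlk1-Dio3 and -0.116 for fibroblast. In proliferation it was 0.135 for other myoblast miRNAs, 0.177 for miR-17, 0.006 for miR-15/16, 0.375 for Dlk1-Dio3, 0.16 for Sfmbt2, 0.686 for blood cell, 0.352 for neuronal and 0.69 for epithelial.

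With Ct under 32, 7 of 77 list medians changed sign. These were let-7 (-0.08) and epithelial (-0.58) in day 1 over day 0, epithelial in day 2 over day 0 (-0.135), blood cell in day 2 over day 1 (-0.17) and day 5 over day 0 (-0.605), and blood cell (0.098) and epithelial (0.205) in proliferation. With the values of the series matrix 1 of 84 changed sign, and without a Ct filter 0 of 84 did.

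Without 1 row, 20 list medians crossed 0. The ranges in day 1 over day 0 were -0.257 to 0.193 for other myoblast miRNAs, -0.225 to 0.083 for miR-17, -0.31 to 0.372 for let-7, -0.053 to 0.427 for Sfmbt2, -0.488 to 0.023 for fibroblast and -0.128 to 0.214 for hepatic. In day 2 over day 0 they were -0.175 to 0.343 for other myoblast miRNAs, -0.253 to 0.179 for miR-17 and -0.039 to 0.555 for fibroblast. In day 2 over day 1 they were -0.015 to 0.461 for other myoblast miRNAs, -0.17 to 0.116 for miR-17, -0.243 to 0.209 for miR-15/16 and -0.269 to 0.396 for blood cell. In day 5 over day 0 they were -0.001 to 0.535 for other myoblast miRNAs and -0.19 to 0.339 for blood cell. In day 5 over day 2 they were -0.178 to 0.177 for other myoblast miRNAs, -0.052 to 0.254 for Dlk1-Dio3 and -0.169 to 0.292 for fibroblast, and in proliferation -0.265 to 0.235 for blood cell and -0.341 to 0.186 for epithelial.

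Of 242 changes of named miRNAs, 9 changed sign after centring and 9 with the global mean, none of them called before or after. After centring and with the global mean, miR-208b was -0.055 and -0.08 in day 1 over day 0 and -0.033 and -0.03 in day 5 over day 2. miR-106b was -0.018 and -0.018 in day 2 over day 0 and -0.243 and -0.223 in day 2 over day 1. miR-21 was -0.073 and -0.073 in day 2 over day 0 and -0.42 and -0.353 in day 5 over day 0. In day 2 over day 1 miR-451 was -0.182 and -0.12 and miR-205 was -0.07 and -0.05, and in day 5 over day 1 miR-682 was -0.654 and -0.616. Direction and call were the same for 204 after centring and 209 with the global mean.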

Other observations

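The values here and the tests behind them, including the choice of the miR-322 group, hairpin arms and miR-30 family, were chosen after the results were seen.

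Neighbours of the X-linked miR-322 hairpin rose early in differentiation, and miR-503 and miR-351 then fell. The hairpins of miR-322, miR-503 and miR-351 lie next to one another in GRCm38.p6, and from day 0 to day 2 they rose together, by 1.86 for miR-322, 2.71 for miR-503 and 1.69 for miR-351. From day 2 to day 5 miR-503 fell by 1.17 (adjusted p = 0.0369) and miR-351 by 1.40 (adjusted p = 0.00651), while miR-322 stood at -0.90 (adjusted p = 0.113, or 0.0087 with the row block). The nearby miR-542 moved otherwise, with miR-542-5p rising by a further 1.11 (adjusted p = 0.035) to 2.26 over day 0 and miR-542-3p at 0.70 (adjusted p = 0.354).

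Arms of 1 hairpin parted in other cases at day 5 over day 0. miR-125b-3p fell by 1.86 while miR-125b-5p stood at 0.05 (adjusted p = 0.941), and miR-125a-3p fell by 1.04 (adjusted p = 0.0127) while miR-125a-5p stood at 0.20. With the global mean miR-125b-5p (adjusted p = 0.00947) and miR-125a-5p (adjusted p = 0.00968) were called lower too. miR-296-3p rose by 3.14 (adjusted p = 0.0033) and miR-296-5p stood at 0.87. Both arms of miR-339 rose, by 2.95 and 3.72. The difference between arms was not itself tested.

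All 5 measured members of the miR-30 family rose at day 5 over day 0, miR-30a by 1.49 (adjusted p = 0.0109), miR-30d by 1.61 (adjusted p = 0.00997), miR-30e by 1.68 (adjusted p = 7.58e-04), miR-30b by 1.09 (adjusted p = 0.0242) and miR-30c by 1.01 (adjusted p = 0.0307). With the global mean, miR-30b and miR-30c were not called (adjusted p = 0.204 and 0.327). miR-26a (1.86), miR-26b (1.46) and miR-24 (1.59) rose as well. These changes lie less than 1 log2 above the panel median of 0.87, so their size depends on the scaling.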
